A study of Mus musculus with 15 samples.

How the data were processed

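Gene expression was measured by RNA sequencing in the midbrain of wild-type BDF1 mice (WT) and of transgenic mice (TG), whose transgene is driven by the Thy1 promoter. There were 15 samples in 5 groups of 3: WT control, WT given 2 mg of carnosine intranasally, TG control, TG given 2 mg of carnosine intranasally, and TG given 10 mM carnosine in the drinking water. Per the labels' protocols, treatment began at 2 months of age and lasted 2 months, total RNA was taken with a mirVana kit, and libraries followed standard Illumina protocols.

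The deposited table holds raw whole-number counts per gene and sample, 1 row for each of 24454 numeric gene IDs, with no normalization. Its columns carry the description given to each sample in the labels, and every column was assigned to its group that way. The aligner, the counting program, the genome build, the annotation and the strand setting are not given in the sources used here. Gene names came from a mouse gene table of assembly GRCm38.p6, which was used for names and for which genes neighbour each other. It named 24374 of the IDs; the 80 others are referred to by number. The unnamed rows held 0.148% to 6.23% of a library's counts, and 4576 rows had 0 counts in every library.

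Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 15818, and libraries were scaled by the trimmed mean of M values (TMM). A quasi-likelihood model with a mean for each of the 5 groups was fitted to all 15 libraries, so that every comparison shares a single estimate of the spread (common biological coefficient of variation 0.244, prior degrees of freedom 6.54). Genes were called at an adjusted p under 0.05 from edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment. Unless another tool is named, an adjusted p for a gene comes from that test. Levels are CPM, counts scaled to the TMM-adjusted library size, and log2 CPM used a prior count of 2.

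Tested were TG control against WT control, WT intranasal against WT control, TG intranasal against TG control, TG drinking water against TG control, TG intranasal against TG drinking water, and the genotype by intranasal interaction. The interaction is the log2 fold change of intranasal carnosine in TG minus that in WT. In addition, 41 gene lists (cell types, pathways and checks) were fixed, of which 38 had at least 3 tested members. They were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Each list was tested again with the correlation estimated from the data. At the preset correlation camera treats members of a list as nearly independent, and no list call in any comparison was kept with an estimated correlation. The groups, the tests, the lists, the rule for naming genes and most of the alternatives were chosen before the data were examined.

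Genes were named by a fixed rule. For each comparison it takes Thy1, the 8 genes called higher and the 8 called lower with the smallest p, and, with fewer than 5 calls, the 5 smallest p as values that did not pass. It adds the 3 members with the smallest p of each list that passed camera, and 2 members each of 6 lists on dopamine neurons, the respiratory chain, carnosine handling, reactive astrocytes, microglia and Nrf2 targets. The rule leaves out predicted genes and pseudogenes among the called genes. Named outside it, and chosen after the data were seen, are Gh, Ttr, Slc6a3, Glo1, Kcnk3, Pcdh11x, Omp, Cyp2a5, Adora2a, S100a8, Malat1, Xist, Ddx3y, Shank1, Dlg4 and Dlgap3; other genes are in places given outside the comparison for which the rule takes them, such as Fos in TG control. Results for some genes that the rule takes are not reported here; they stayed in every fit, test and count.

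The procedure was tested on simulated counts for TG control against WT control with 15670 genes. It recovered 56 of 100 genes changed by a fold of 2 and 90 of 100 changed by a fold of 4, with 4 false calls among 150, and made 0 edgeR calls in an unchanged comparison. In a second simulation with 15681 genes, camera called a raised list of 50 genes with an adjusted p of 2.45e-27, and 6.81e-06 with an estimated correlation. It called 0 of 38 unchanged lists. The simulated genes were drawn independently of each other, and unchanged libraries differed only in depth and scaling. Neither simulation can therefore show how often edgeR calls unchanged genes in the real libraries. Nor can they show how often camera calls unchanged lists of correlated genes.

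The alternatives were DESeq2 1.42.0 with its own Wald test, RLE (DESeq2's size factors) or upper-quartile scaling, voom with sample quality weights, no filter or a stricter filter of 5 CPM, an adjusted p of 0.1, a minimum absolute log2 fold change of 1 for called genes, a fit of the compared groups only, a block for the replicate number, and leaving out each library in turn. Added after the data were seen were a loess correction (span 0.3) for transcript length and GC content, a term for a split between libraries, leaving out the rows that mark that split, leaving out 2 libraries rich in pituitary transcripts, limma's fry, and a comparison of the genotypes over control and intranasal libraries together. Named genes were planned to be followed under RLE scaling, DESeq2, the block and left-out libraries, and were afterwards followed under the other settings too. Comparisons that share the TG control libraries were set beside 20 simulated data sets, or 10 for the overlap of calls, in which nothing changed.

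Total counts ranged from 13202199 to 60542423 per library and 16120 to 17874 genes had at least 1 count. Where a group had 0 counts of a gene, the fold is a lower bound against 3 counts over the group; such floors cover counting error only. Within groups, log2 CPM correlated at 0.946 to 0.987 between libraries, and no pair of columns was identical. Nothing in the labels says that the libraries of a group come from separate animals, so p-values measure only the spread between these samples. The 3 lists with fewer than 3 tested members were not tested as lists.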

Results

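RNA was sequenced from 15 midbrain samples of WT and TG mice, 3 per group. Carnosine, a dipeptide of beta-alanine and histidine, was given to WT mice by the nose and to TG mice by the nose or in the drinking water. Libraries held 13202199 to 17759834 counts in WT control, 25676560 to 60542423 in WT intranasal, 14078637 to 17347311 in TG control, 23055862 to 34843691 in TG intranasal and 16256593 to 23919657 in TG drinking water. Values are means ± SD over the 3 libraries of a group.

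The libraries also differ in ways the groups do not explain. The most abundant of the unnamed rows held 2.31% to 6.22% of the counts in 8 libraries, namely all 6 WT libraries and TG control 1 and 2. It held 0.122% to 0.3204% in the other 7, namely TG control 3 and all 6 TG carnosine libraries. The descriptions that name the columns number the samples, and in that numbering the 8 libraries come first and the other 7 follow. Whether this order marks a step of processing is not given in the labels and was not tested. Lars2, a mitochondrial leucyl-tRNA synthetase, followed the same split, at 0.377% to 1.09% against 0.0145% to 0.0419%. Both rows, with Mir6236 and Mir6240, were treated as ribosomal-RNA-like when the rows that mark the split were left out. Whether their counts come from ribosomal RNA was not tested. Gh, the pituitary growth hormone, reached 718 CPM in WT control 1 and 557 CPM in TG control 1, against 1.22 to 121 CPM in the others.

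The comparison of TG control with WT control asks what the transgene changes without carnosine. Thy1 (gene ID 21838), whose promoter drives the transgene, rose from 634 ± 88.1 to 3878 ± 517 CPM, a log2 fold change of 2.61 (SE 0.18). Every one of the 9 TG libraries lay above every one of the 6 WT libraries. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 2 genes were called, both higher in TG control, with adjusted p = 1.60e-06 for Thy1. An unadjusted p under 0.05 was reached by 2859 genes, and DESeq2 called 421. In a fit of the 6 compared libraries only the count was 1. With a block for the replicate number it was 531, of which 401 were lower.

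**Figure D1:**
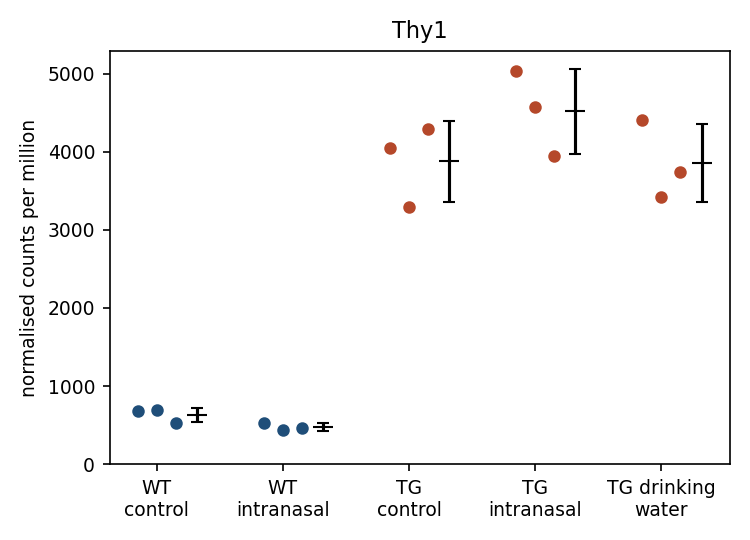
Levels of Thy1 in normalised CPM for each group on the horizontal axis. Points are libraries (blue WT, red TG) and black bars are the mean ± SD of 3 libraries; every TG library lies above every WT library.

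Genes of energy metabolism and protein synthesis fell as groups in TG control. Of 76 nuclear-encoded subunits of the respiratory chain, 75 were lower in TG control, with a median log2 fold change of -0.66 (camera adjusted p = 1.22e-27, adjusted p = 0.628 with an estimated correlation). None passed over all genes tested and 46 did when adjusted over the list alone; Ndufb2 of complex I was at -1.38 (SE 0.31) and Atp5e of the ATP synthase at -1.48 (SE 0.34). Cytosolic ribosomal proteins fell with a median of -0.83, 76 of 78 being lower, as in Rps14 at -1.92 (SE 0.41) (camera adjusted p = 3.71e-25, adjusted p = 0.628 with an estimated correlation). Mitochondrial ribosomal proteins fell with a median of -0.47, 76 of 78 being lower, as in Mrps11 at -0.80 (SE 0.17) (camera adjusted p = 9.15e-20, adjusted p = 0.628 with an estimated correlation). Proteasome subunits fell too, with a median of -0.36 and 35 of 39 lower (camera adjusted p = 3.21e-09, adjusted p = 0.641 with an estimated correlation). Antioxidant enzymes, such as Prdx5 at -0.63 (SE 0.18), fell with a median of -0.48 and 15 of 17 lower (camera adjusted p = 7.15e-05, adjusted p = 0.628 with an estimated correlation). Adjusted over the list alone, 35 cytosolic and 21 mitochondrial ribosomal genes, 3 proteasome genes and 7 antioxidant genes were lower. Without TG control 2 the medians were -0.419 for the respiratory chain, -0.286 for mitochondrial ribosomal proteins, -0.204 for the proteasome and -0.304 for antioxidant enzymes, and without WT control 1 they were -0.437 for the respiratory chain and -0.271 for mitochondrial ribosomal proteins. After a correction for transcript length and GC content the medians were -0.111 for the respiratory chain (upper quartile 0.0024), -0.306 and -0.117 for cytosolic and mitochondrial ribosomal proteins, -0.0698 for the proteasome and -0.156 for antioxidant enzymes. Across 13616 genes, which are not independent replicates, log2 fold change and transcript length had a Spearman rho of 0.644. The respiratory-chain genes are short, with a median transcript length of 913 bases against 3162 for all genes.

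Lists of oligodendrocyte precursor, microglial and astrocyte markers rose in TG control, while oligodendrocyte markers, with a median of -0.023 (camera adjusted p = 0.691), did not pass. All 8 markers of oligodendrocyte precursors were higher in TG control, with a median of 0.96 (camera adjusted p = 0.000124, adjusted p = 0.628 with an estimated correlation), and 5 passed when adjusted over the list alone; the growth factor Bmp4 was at 1.29 (SE 0.30). The precursor median was 0.370 without TG control 2 and 0.454 after the length and GC correction. Microglial markers rose with a median of 0.34 (camera adjusted p = 0.0201, adjusted p = 0.724 with an estimated correlation), but they were not uniform, with Itgam at 1.15 (SE 0.30) and Tyrobp at -0.78 (SE 0.27). The microglial call was lost without WT control 2 (median 0.310, adjusted p = 0.184) or TG control 1 (median 0.211, adjusted p = 0.510). After the length and GC correction the microglial median was 0.529 (camera adjusted p = 3.48e-11 at the preset correlation). Genes of microglial activation rose with a median of 0.44 (camera adjusted p = 0.00600, adjusted p = 0.628 with an estimated correlation). Without TG control 1 (median 0.341, adjusted p = 0.0880) they lost the call. The median was 0.775 without WT control 1, 0.815 without WT control 3 and 0.692 without TG control 3, and 0.861 after the length and GC correction. Astrocyte markers rose with a median of 0.41 (camera adjusted p = 0.0458, adjusted p = 0.700 with an estimated correlation). Astrocyte markers lost the call without WT control 1 (median 0.221, adjusted p = 0.396) or TG control 2 (median 0.0999, adjusted p = 0.335). Immediate early genes, which respond to neuronal activity, rose with a median of 1.00 and 16 of 16 higher (camera adjusted p = 0.000332, adjusted p = 0.654 with an estimated correlation). Their call was lost without TG control 1 (median 0.302, adjusted p = 0.556), the library in which Fos reached 176 CPM. Without WT control 1 and TG control 1, the libraries rich in pituitary transcripts, calls were lost for microglial markers (median 0.113, adjusted p = 0.746), genes of microglial activation (0.261, adjusted p = 0.1498), astrocyte markers (0.358, adjusted p = 0.181) and immediate early genes (0.0896, adjusted p = 0.951).

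A further 4 lists passed at the preset correlation and were lost in some fits with a library left out. Choroid plexus genes rose with a median of 0.62 (camera adjusted p = 0.00489, adjusted p = 0.654 with an estimated correlation). Without WT control 1 (median 0.159, adjusted p = 0.430) or TG control 3 (median 0.278, adjusted p = 0.0588) they lost the call. The median was 1.58 without WT control 3 and 0.927 without TG control 2. Meningeal fibroblast genes rose with a median of 0.59 (camera adjusted p = 0.00600, adjusted p = 0.654 with an estimated correlation). Fibroblast genes lost the call without WT control 2 (median 0.538, adjusted p = 0.0614). The median was 0.392 without TG control 2. Circadian clock genes rose with a median of 0.29 (camera adjusted p = 0.0465, adjusted p = 0.654 with an estimated correlation). Without WT control 1 (median 0.168, adjusted p = 0.396), WT control 3 (median 0.207, adjusted p = 0.104) or TG control 3 (median 0.187, adjusted p = 0.135) they lost the call. Autophagy and lysosome genes fell with a median of -0.088 (camera adjusted p = 0.0465, adjusted p = 0.628 with an estimated correlation). Autophagy and lysosome genes lost the call without WT control 2 (median -0.0585, adjusted p = 0.0768), WT control 3 (median -0.0761, adjusted p = 0.109), TG control 1 (median -0.0589, adjusted p = 0.0744) or TG control 3 (median -0.138, adjusted p = 0.115). Circadian clock genes (median 0.0740, camera adjusted p = 0.362) and autophagy and lysosome genes (-0.0779, 0.0546) did not pass after the length and GC correction. With a term for the library split choroid plexus (0.287, 0.0677), circadian clock (0.199, 0.133) and autophagy genes (-0.128, 0.133) did not. Without both pituitary-rich libraries choroid plexus genes (median 0.172, adjusted p = 0.746) and circadian clock genes (0.230, adjusted p = 0.181) did not pass. Reactive astrocyte genes, with a median of 0.37 (camera adjusted p = 0.146), and Nrf2 targets, with a median of -0.11 (camera adjusted p = 0.284), did not pass. Nor did markers of dopamine neurons, the cells lost in Parkinson's disease: their median was -0.14 and their mean 0.049, with camera pointing up at adjusted p = 0.872.

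The comparison of WT intranasal with WT control asks what carnosine changes in normal midbrain. Of 159 genes called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 51 rose and 108 fell, each with an adjusted p of at least 0.0467. Among those that rose were endothelial and connective tissue genes: thrombomodulin, Thbd, by a log2 fold change of 1.87 (SE 0.29); the scavenger receptor Stab2, by 3.59 (SE 0.57); and the collagen-binding proteoglycan Fmod, by 2.31 (SE 0.39). Bmp6 rose by 1.35 (SE 0.23) and Gpr183, an oxysterol receptor of immune cells, by 2.28 (SE 0.43). Among those that fell were Oaz1, a regulator of polyamine synthesis, at -1.38 (SE 0.23), the pro-apoptotic Bad at -1.04 (SE 0.20), and the neuronal non-coding RNA Bc1, from 7509 ± 4205 to 1141 ± 302 CPM. An unadjusted p under 0.05 was reached by 3796 genes and DESeq2 called 1423. The count was 0 by edgeR without WT control 1, WT intranasal 2 or WT intranasal 3, 346 without WT control 3 and 960 without WT intranasal 1. It was 0 with upper-quartile scaling, 0 with a term for the library split, 0 without the rows that mark the split, 2 in a fit of the 6 compared libraries only and 7 after the length and GC correction. All 6 WT libraries lie on the same side of the split, so the split term cannot adjust this comparison. The respiratory-chain median was -0.855 with or without it, and the term acts here only through the shared estimate of the spread.

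Gene groups of energy metabolism and protein synthesis fell in WT intranasal. The 3 WT control libraries are the same as those set against TG control, so agreement with that comparison is expected in part without any change. All 76 respiratory-chain subunits were lower, with a median of -0.86, 11 called over all genes and 70 adjusted over the list alone (camera adjusted p = 5.36e-34, adjusted p = 0.559 with an estimated correlation). Ndufb2 fell, with a log2 fold change of -1.60 (SE 0.31), as did Atp5e at -1.66 (SE 0.34). Cytosolic ribosomal proteins fell with a median of -0.98, 77 of 78 lower, 2 called and 67 adjusted over the list alone (camera adjusted p = 3.14e-26, adjusted p = 0.559 with an estimated correlation). Mitochondrial ribosomal proteins fell with a median of -0.51, all 78 lower, 7 called and 43 adjusted over the list alone (camera adjusted p = 4.86e-20, adjusted p = 0.559 with an estimated correlation). Proteasome subunits fell with a median of -0.37 (camera adjusted p = 1.29e-08, adjusted p = 0.623 with an estimated correlation), led by the immunoproteasome subunit Psmb10 at -1.04 (SE 0.24). Antioxidant enzymes fell with a median of -0.56, 14 of 17 lower (camera adjusted p = 0.000438, adjusted p = 0.559 with an estimated correlation), 9 lower and 1 higher when adjusted over the list alone. After the length and GC correction the medians were -0.169 for the respiratory chain, -0.336 and -0.123 for cytosolic and mitochondrial ribosomal proteins, -0.0519 for the proteasome and -0.224 for antioxidant enzymes, and the last 2 lists did not pass (adjusted p = 0.0593 and 0.0760). Log2 fold change and transcript length had a Spearman rho of 0.669 across genes, and WT control 1 had the highest respiratory-chain and ribosomal levels of the WT libraries.

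**Figure D2:**
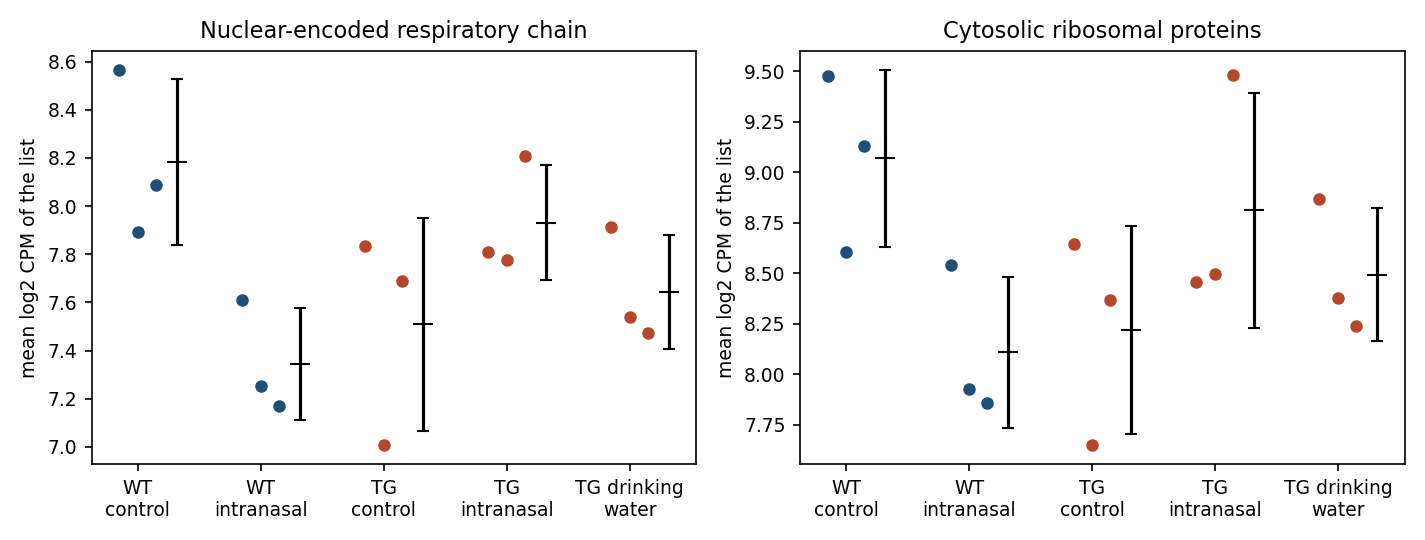
Mean log2 CPM over the nuclear-encoded respiratory-chain genes (left) and the cytosolic ribosomal protein genes (right) for each group on the horizontal axis. Points are libraries (blue WT, red TG) and black bars are the mean ± SD of 3 libraries; the respiratory-chain means are 8.18 in WT control, 7.34 in WT intranasal and 7.51 in TG control.

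Of the lists tested, 7 rose in WT intranasal. Oligodendrocyte markers, with a median of -0.082 (camera adjusted p = 0.512), and microglial markers, with 0.21 (camera adjusted p = 0.431), did not pass. All 10 meningeal fibroblast genes were higher, with a median of 1.12, 3 called and 8 adjusted over the list alone (camera adjusted p = 1.74e-06, adjusted p = 0.559 with an estimated correlation); Aebp1 rose by 1.61 (SE 0.32) and the collagen gene Col1a2 by 1.23 (SE 0.28). Oligodendrocyte precursor markers rose with a median of 0.93, all 8 higher and Bmp4 called at 1.43 (SE 0.30) (camera adjusted p = 0.000514, adjusted p = 0.559 with an estimated correlation). Genes of microglial activation rose with a median of 0.74 (camera adjusted p = 0.0105, adjusted p = 0.559 with an estimated correlation), including the antigen-presenting H2-Eb1 at 2.08 (SE 0.48); their median was 0.435 without WT intranasal 3 and 1.18 after the length and GC correction, which gave 0.525 for the precursor markers. Cerebellar neuron genes rose with a median of 1.63 and all 10 higher (camera adjusted p = 0.00113, adjusted p = 0.559 with an estimated correlation). Gabra6 was at 14.4 and 18.6 CPM in WT intranasal 2 and 3. The mean log2 CPM of the list was 3.98 and 4.34 in these libraries and 1.26 in WT intranasal 1, within the 1.09 to 1.58 of WT control. Astrocyte markers rose with a median of 0.55 (camera adjusted p = 0.0105, adjusted p = 0.698 with an estimated correlation). Astrocyte markers lost the call without WT control 1 (median 0.418, adjusted p = 0.0977). Vascular genes rose with a median of 0.44 (camera adjusted p = 0.0271, adjusted p = 0.847 with an estimated correlation). Without WT control 2 (median 0.286, adjusted p = 0.174) or WT intranasal 1 (median 0.443, adjusted p = 0.123) they lost the call. A replicate block ended it too (camera adjusted p = 0.0521). The median was 0.690 without WT control 3. Choroid plexus genes rose with a median of 0.40 (camera adjusted p = 0.0190, adjusted p = 0.847 with an estimated correlation). Without WT control 1 (median -0.0783, adjusted p = 0.737) or WT intranasal 1 (median 0.0207, adjusted p = 0.200) they lost the call. Their median was 0.229 without WT control 2, 1.49 without WT control 3, 0.691 without WT intranasal 2 and 0.724 without WT intranasal 3, and the growth factor gene Igf2 was called at 1.17 (SE 0.24).

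The interaction asks whether intranasal carnosine acts differently in TG and WT mice. It called 367 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment: for 225 the log2 fold change was higher in TG than in WT and for 142 it was lower. The count was 0 with a term for the library split, 0 in a fit of the 12 compared libraries only and 1 after the length and GC correction. Lrrc17, a secreted leucine-rich repeat protein, had the smallest p and differed by 5.94 (SE 0.79) (adjusted p = 0.0154). With the split term Lrrc17 differed by 5.39 (SE 1.07) and did not pass (adjusted p = 0.296), as its error grew. It was at 22.7 ± 4.04 and 6.34 ± 1.99 CPM in WT control and WT intranasal, and at 5.62 ± 2.61 and 96.8 ± 70.1 CPM in TG control and TG intranasal. The non-coding RNA Bc1 differed by 3.90 (SE 0.70). In the other direction, the transcription factor Zbtb20 differed by -3.08 (SE 0.58) and the glucose transporter Slc2a12 by -2.26 (SE 0.46). The astrocyte glutamate transporter Slc1a2 differed by -2.68 (SE 0.66) and the bicarbonate transporter Slc4a4 by -2.13 (SE 0.51). Cdr1 differed by -3.59 (SE 0.68); it followed the library split, at 95.7 to 177 CPM in its 8 libraries and 3.11 to 38.5 CPM in the other 7.

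The lists that fell in WT intranasal had positive differences, which subtracting the WT change favours. The median was 1.298 for the respiratory chain, with 25 of 76 genes called and 72 adjusted over the list alone (camera adjusted p = 1.96e-33, adjusted p = 0.650 with an estimated correlation). It was 1.63 for cytosolic ribosomal proteins, with 6 called and 72 adjusted over the list alone (camera adjusted p = 2.19e-29, adjusted p = 0.650 with an estimated correlation). It was 0.95 for mitochondrial ribosomal proteins, with 10 called and 57 adjusted over the list alone (camera adjusted p = 1.83e-24, adjusted p = 0.650 with an estimated correlation). It was 0.70 for the proteasome (camera adjusted p = 1.12e-12, adjusted p = 0.650 with an estimated correlation) and 0.82 for antioxidant enzymes (camera adjusted p = 0.000139, adjusted p = 0.650 with an estimated correlation), with Gpx4, which reduces lipid peroxides, called at 1.73 (SE 0.43). Astrocyte markers had a median of -1.09 (camera adjusted p = 0.00202, adjusted p = 0.727 with an estimated correlation) and oligodendrocyte precursor markers of -1.11 (camera adjusted p = 0.00344, adjusted p = 0.703 with an estimated correlation); the astrocyte median was -0.662 without TG control 2. After the length and GC correction the medians were 0.233 for the respiratory chain, 0.550 and 0.230 for cytosolic and mitochondrial ribosomal proteins, 0.162 for the proteasome, 0.258 for antioxidant enzymes, which did not pass (adjusted p = 0.0526), and -0.542 for precursor markers. With the split term precursor markers (median -0.671, camera adjusted p = 0.0549) and immediate early genes (-0.645, 0.142) did not pass. The other lists passed with it at the preset correlation. Their medians were 1.16 for the respiratory chain, 1.55 and 0.789 for cytosolic and mitochondrial ribosomal proteins and 0.631 for the proteasome. They were 0.675 for antioxidant enzymes, -0.630 for astrocyte markers and -1.21 for choroid plexus genes. Spearman's rho with transcript length was -0.700 across genes, and the 3 TG intranasal libraries lie on the other side of the library split from WT and from TG control 1 and 2.

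The interaction count moved with single libraries. It was 1 without WT control 1, TG intranasal 1 or TG intranasal 3, 0 without WT intranasal 2 or 3, TG control 2 or TG intranasal 2, and 19 without TG control 3. It was 1999 without WT control 2, 1913 without WT intranasal 1 and 2389 without TG control 1. An unadjusted p under 0.05 was reached by 4527 genes and DESeq2 called 2396. Choroid plexus genes, with a median difference of -0.75 (camera adjusted p = 0.0273, adjusted p = 0.825 with an estimated correlation), lost their call without WT control 1 (median -0.354, adjusted p = 0.279), WT intranasal 1 (median -0.411, adjusted p = 0.130), TG control 1 (median -0.829, adjusted p = 0.0912), TG control 3 (median -0.425, adjusted p = 0.0806), TG intranasal 1 (median -0.569, adjusted p = 0.0598) or TG intranasal 2 (median -0.372, adjusted p = 0.162). The median was -1.67 without WT control 3 and -1.38 without TG intranasal 3. Immediate early genes, at -1.57 (camera adjusted p = 0.00178, adjusted p = 0.825 with an estimated correlation), lost their call without TG control 1 (median -0.751, adjusted p = 0.134). Without both pituitary-rich libraries the interaction called 669 genes, and choroid plexus genes (median -0.398, adjusted p = 0.448) and immediate early genes (-0.532, adjusted p = 0.346) did not pass.

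The comparison of TG intranasal with TG control asks what nasal carnosine changes in mice with the transgene. Lrrc17 (gene ID 74511) rose from 5.62 ± 2.61 to 96.8 ± 70.1 CPM, a log2 fold change of 4.09 (SE 0.58). Its levels were 16.7, 127 and 147 CPM in the 3 treated libraries and 5.49, 3.08 and 8.30 CPM in the controls. Thy1 did not pass, at 0.22 (SE 0.17). Lrrc17 was the 1 gene called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0385), with 1541 genes at an unadjusted p under 0.05 and 14 called by DESeq2. The count was 0 by edgeR without TG control 1 or 2, TG intranasal 2 or 3 or TG drinking water 1, 2 or 3, whose group is not compared here but enters the spread, and 8 without TG control 3. It was 91, of which 85 were lower, without WT control 1 and TG control 1, the libraries rich in pituitary transcripts. The call of Lrrc17 was lost with a term for the library split, at 3.54 (SE 0.90, adjusted p = 0.452) with a larger error, in a fit of the 6 compared libraries only (4.10, adjusted p = 0.469), by voom (3.59, adjusted p = 0.491) and with a replicate block (4.06, adjusted p = 0.0509). The 1 gene called with the split term was lower. Cdr1, at -3.17 (SE 0.51) (adjusted p = 0.0808), and Lars2, at -3.61 (SE 0.66) (adjusted p = 0.145), did not pass and follow the library split. Wdr63 had 0 counts in TG intranasal and was at least 19.7-fold lower than in TG control (adjusted p = 0.145), where its mean was 0.636 CPM.

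Ribosomal, respiratory-chain and proteasome genes were higher as groups in TG intranasal. Of 76 respiratory-chain genes 75 were higher, with a median of 0.40 (camera adjusted p = 3.70e-18, adjusted p = 0.734 with an estimated correlation). Cytosolic ribosomal proteins rose with a median of 0.62 (camera adjusted p = 1.51e-19, adjusted p = 0.734 with an estimated correlation), mitochondrial ribosomal proteins with 0.34 (camera adjusted p = 3.70e-18, adjusted p = 0.734 with an estimated correlation) and proteasome subunits with 0.34 (camera adjusted p = 3.78e-12, adjusted p = 0.734 with an estimated correlation). Antioxidant enzymes rose with a median of 0.28 (camera adjusted p = 0.00257, adjusted p = 0.734 with an estimated correlation). Antioxidant enzymes lost the call without TG control 2 (median 0.0570, adjusted p = 0.0975). Immediate early genes fell with a median of -1.43, all 16 lower and 10 adjusted over the list alone, as in Nr4a1 at -1.74 (SE 0.48) and Arc at -1.45 (SE 0.43) (camera adjusted p = 4.89e-08, adjusted p = 0.734 with an estimated correlation). Without TG control 1 (median -0.344, adjusted p = 0.0937) they lost the call. Astrocyte markers fell with a median of -0.50 and 11 of 12 lower (camera adjusted p = 0.00313, adjusted p = 0.734 with an estimated correlation). Astrocyte markers lost the call without TG control 2 (median -0.188, adjusted p = 0.0975) or TG intranasal 1 (median -0.453, adjusted p = 0.0775). Meningeal fibroblast genes rose with a median of 0.29 (camera adjusted p = 0.0172, adjusted p = 0.759 with an estimated correlation). Fibroblast genes lost the call without TG control 1 (median 0.319, adjusted p = 0.0558), TG control 3 (median 0.120, adjusted p = 0.252) or TG intranasal 1 (median 0.156, adjusted p = 0.183). The median was 0.614 without TG control 2. Without TG control 2 the medians were 0.167 for the respiratory chain, 0.384 and 0.172 for cytosolic and mitochondrial ribosomal proteins and 0.190 for the proteasome, and without TG intranasal 3 they were 0.243 for the respiratory chain and 0.222 for cytosolic ribosomal proteins. After the length and GC correction respiratory-chain genes (median 0.0518, adjusted p = 0.113) and antioxidant enzymes (0.0508, adjusted p = 0.379) did not pass, and the medians were 0.276 and 0.110 for cytosolic and mitochondrial ribosomal proteins and 0.0878 for the proteasome. With the split term meningeal fibroblast genes had a larger median of 0.781 (camera adjusted p = 7.94e-05). The respiratory chain (0.267), cytosolic (0.563) and mitochondrial ribosomal proteins (0.243) and the proteasome (0.239) passed too. Astrocyte markers (median -0.173, adjusted p = 0.428), antioxidant enzymes (0.179, 0.0811) and immediate early genes (-0.368, 0.103) did not pass with it. Without both pituitary-rich libraries meningeal fibroblast genes (median 0.3197, adjusted p = 0.0785) and immediate early genes (-0.343, adjusted p = 0.111) did not. Spearman's rho with transcript length was -0.557 across genes. Genes of carnosine handling did not pass, with a median of -0.12 (camera adjusted p = 0.462).

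The comparison of TG drinking water with TG control asks the same for carnosine taken by mouth. Lrrc17 rose again, to 112 ± 25.6 CPM, a log2 fold change of 4.30 (SE 0.59), and Thy1 did not pass, at -0.0078 (SE 0.17). Lrrc17 was the 1 gene called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0228), with 1277 genes at an unadjusted p under 0.05 and 196 called by DESeq2. Hes5, a Notch target of neural progenitors and astrocytes, was at -1.03 (SE 0.18) and did not pass (adjusted p = 0.109). Lars2 and Mir6240, which follow the library split, were at -3.94 (SE 0.67) and -4.39 (SE 0.68) and did not pass; all 3 TG drinking water libraries lie on the side of the split where 1 of the 3 TG controls lies. The count was 0 by edgeR without TG control 1 or 2 or TG drinking water 2, 8 without TG control 3 and 2 without TG drinking water 1 or TG intranasal 3. It was 188, of which 179 were lower, without both pituitary-rich libraries. With a term for the library split it was 43, all lower, and Lrrc17 lost its call, at 3.75 (SE 0.91, adjusted p = 0.105) with a larger error.

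**Figure D3:**
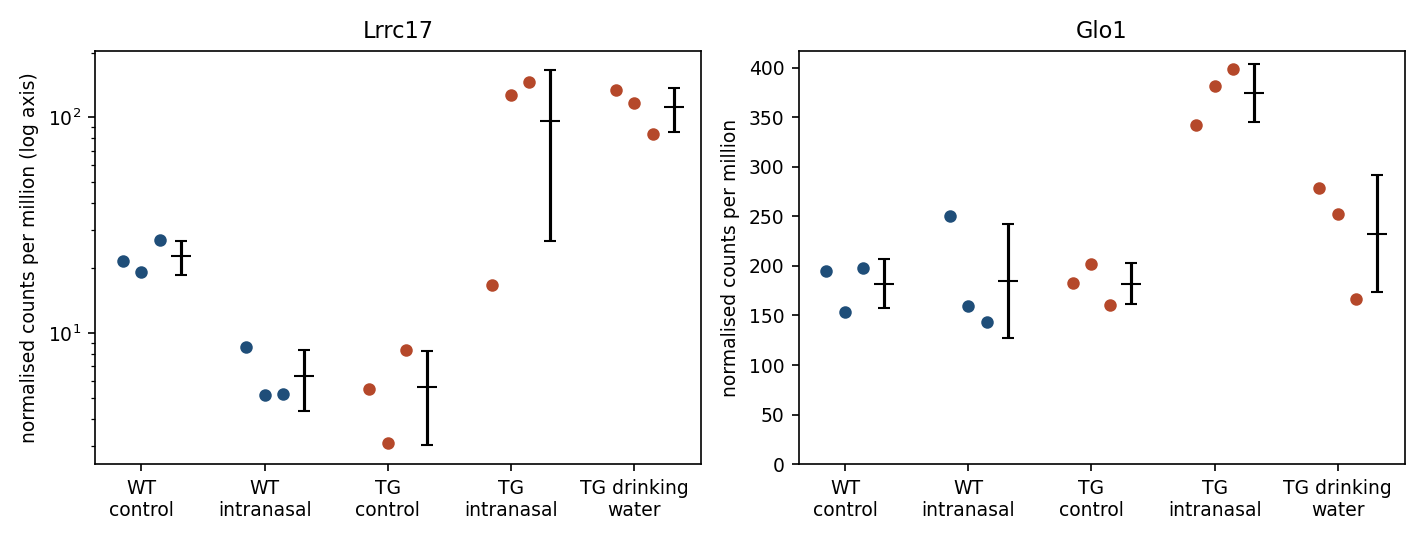
Levels of Lrrc17 (left, log axis) and Glo1 (right) in normalised CPM for each group on the horizontal axis. Points are libraries (blue WT, red TG) and black bars are the mean ± SD of 3 libraries; Lrrc17 lies between 16.7 and 147 CPM in the 6 TG carnosine libraries, above all 3 TG control libraries.

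Stress-response genes rose as groups in TG drinking water. All 15 heat shock genes were higher, with a median of 0.28 and 3 adjusted over the list alone (camera adjusted p = 6.70e-05, adjusted p = 0.623 with an estimated correlation); the chaperones Hspa1a and Dnajb1 were at 1.90 (SE 0.55) and 0.80 (SE 0.23), and the co-chaperone Bag3 at 0.62 (SE 0.17). All 17 genes of the unfolded protein response were higher, with a median of 0.32 (camera adjusted p = 6.70e-05, adjusted p = 0.623 with an estimated correlation), among them the chaperone Hspa5 at 0.63 (SE 0.25) and Herpud1 at 0.59 (SE 0.17). These were the 2 of 17 called lists that kept their call without each library in turn, and the median of the unfolded protein response was 0.189 without TG drinking water 2. In mean log2 CPM heat shock genes were at 7.36 and 7.69 in TG drinking water 1 and 2 and at 6.87 in TG drinking water 3, within the 6.73 to 7.01 of TG control. Genes of the unfolded protein response were at 5.46 and 5.37 in the former and 4.87 in the latter, against 4.79 to 4.84 in TG control.

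The other 15 lists lost their call or turned without at least 1 library. Astrocyte markers fell with a median of -0.43, all 12 lower (camera adjusted p = 6.70e-05, adjusted p = 0.623 with an estimated correlation). Astrocyte markers lost the call without TG control 2 (median -0.235, adjusted p = 0.117). Dopamine neuron markers rose with a median of 0.85 (camera adjusted p = 0.00264, adjusted p = 0.623 with an estimated correlation), as in Ddc, an enzyme of dopamine synthesis, at 0.85 (SE 0.32). Dopamine neuron markers lost the call without TG control 3 (median 0.530, adjusted p = 0.217). Choroid plexus genes rose with a median of 0.57 (camera adjusted p = 0.00119, adjusted p = 0.623 with an estimated correlation). Without TG control 2 (median 0.332, adjusted p = 0.1003) they lost the call. The median was 0.962 without TG control 3. Forebrain neuron markers fell with -0.32 (camera adjusted p = 0.0146, adjusted p = 0.623 with an estimated correlation). Without TG control 2 (median -0.249, adjusted p = 0.307) they lost the call. Cerebellar genes rose with 0.91 (camera adjusted p = 0.00641, adjusted p = 0.623 with an estimated correlation); their median was 1.43 without TG control 2, and the call was lost without TG drinking water 3 (median 0.349, adjusted p = 0.253), where Gabra6 was at 12.6 CPM. Meningeal fibroblast genes rose with 0.43 (camera adjusted p = 0.000476, adjusted p = 0.623 with an estimated correlation). Fibroblast genes lost the call without TG drinking water 3 (median 0.203, adjusted p = 0.1498). Oligodendrocyte genes rose with 0.31 (camera adjusted p = 0.00538, adjusted p = 0.626 with an estimated correlation). Oligodendrocyte genes lost the call without TG control 3 (median 0.193, adjusted p = 0.222). The median was 0.477 without TG control 1 and 0.187 without TG drinking water 1. Vascular genes rose with 0.26 (camera adjusted p = 0.00614, adjusted p = 0.623 with an estimated correlation). Without TG control 3 (median 0.109, adjusted p = 0.240) or TG drinking water 3 (median 0.0974, adjusted p = 0.181) they lost the call. The median was 0.693 without TG control 2. Thalamic markers rose with 0.50 (camera adjusted p = 0.0376, adjusted p = 0.623 with an estimated correlation). Without TG control 2 (median 0.438, adjusted p = 0.161), TG control 3 (median 0.364, adjusted p = 0.166) or TG drinking water 1 (median 0.520, adjusted p = 0.172) they lost the call. A replicate block ended it too (camera adjusted p = 0.0586).

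Interferon response genes rose with 0.32 (camera adjusted p = 0.0127, adjusted p = 0.623 with an estimated correlation). Interferon genes lost the call without TG control 3 (median 0.227, adjusted p = 0.173) or TG drinking water 1 (median 0.234, adjusted p = 0.0887). Glucocorticoid response genes rose with 0.45 (camera adjusted p = 0.0170, adjusted p = 0.623 with an estimated correlation). Without TG drinking water 1 (median 0.0545, adjusted p = 0.712) they lost the call. Mitochondrial ribosomal proteins rose with 0.15 (camera adjusted p = 6.70e-05, adjusted p = 0.697 with an estimated correlation). Mitochondrial ribosomal proteins lost the call without TG control 2 (median -0.0371, adjusted p = 0.467) or TG drinking water 1 (median 0.0387, adjusted p = 0.103). The median was 0.282 without TG control 1. Cytosolic ribosomal proteins rose with 0.23 (camera adjusted p = 6.70e-05, adjusted p = 0.697 with an estimated correlation). Without TG control 2 (median -0.00915, adjusted p = 0.581) or TG drinking water 1 (median 0.0111, adjusted p = 0.359) they lost the call. The median was 0.488 without TG control 1 and 0.353 without TG drinking water 3. Proteasome genes rose with 0.18 (camera adjusted p = 6.70e-05, adjusted p = 0.626 with an estimated correlation). Proteasome genes lost the call without TG control 2 (median 0.0434, adjusted p = 0.561). The median was 0.272 without TG control 1 and 0.105 without TG drinking water 1. Respiratory-chain genes rose with 0.11 (camera adjusted p = 0.0146, adjusted p = 0.786 with an estimated correlation). Without TG drinking water 1 (median -0.0364, adjusted p = 0.841) they lost the call; without TG control 2 they fell, with a median of -0.097 and adjusted p = 0.00705. Their median was 0.299 without TG control 1, 0.194 without TG control 3 and 0.196 without TG drinking water 3. After the length and GC correction respiratory-chain (median -0.0347, camera adjusted p = 0.178), mitochondrial (0.0561, 0.151) and cytosolic ribosomal (0.106, 0.0687), forebrain (-0.158, 0.0687), thalamic (0.482, 0.0834) and interferon genes (0.309, 0.0941) did not pass. The thalamic and interferon medians were close to those without the correction. With the split term respiratory-chain (adjusted p = 0.347), mitochondrial (0.495) and cytosolic ribosomal (0.333), proteasome (0.154), forebrain (0.126, median -0.325), astrocyte (0.242), choroid plexus (0.347) and glucocorticoid response genes (0.114) did not. The other lists passed with it. Their medians were larger than without it for dopamine neuron (1.75), cerebellar (1.94), thalamic (0.695), interferon (0.674), oligodendrocyte (0.696), vascular (0.905) and meningeal fibroblast genes (0.903). They were smaller for heat shock (0.194) and unfolded protein response genes (0.180).

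The comparison of TG intranasal with TG drinking water asks whether the routes differ. Of 38 lists, 18 passed camera, 6 higher and 12 lower in TG intranasal, and 6 of the 18 kept their call without each library in turn; the other 12 are given here only as a count. Immediate early genes were lower in TG intranasal with a median of -1.26, all 16 lower and 6 adjusted over the list alone, as in Nr4a3 at -2.09 (SE 0.52) (camera adjusted p = 1.55e-08, adjusted p = 0.641 with an estimated correlation); the median was -0.414 without TG drinking water 1. Dopamine neuron markers were lower with a median of -0.65, 16 of 18 lower (camera adjusted p = 0.000220, adjusted p = 0.641 with an estimated correlation), as in Lmx1a, a transcription factor of these neurons, at -3.03 (SE 0.72) (gene adjusted p = 0.511). Thalamic markers were lower with a median of -0.72 (camera adjusted p = 6.89e-06, adjusted p = 0.641 with an estimated correlation) and choroid plexus genes with -0.79, all 12 lower (camera adjusted p = 1.07e-06, adjusted p = 0.641 with an estimated correlation); the choroid plexus median was -0.510 without TG intranasal 2 and -1.63 without TG intranasal 3. Respiratory-chain genes were higher with a median of 0.28, all 76 higher (camera adjusted p = 1.10e-10, adjusted p = 0.641 with an estimated correlation), and mitochondrial ribosomal proteins with 0.20 (camera adjusted p = 8.21e-07, adjusted p = 0.672 with an estimated correlation). Their medians were 0.123 and 0.108 without TG intranasal 3, 0.436 and 0.313 without TG drinking water 1, and 0.0840 and 0.0676 after the length and GC correction; the mitochondrial ribosomal median was 0.117 without TG drinking water 3. Choroid plexus transcript Ttr ranged from 49.9 to 1977 CPM over the 15 libraries and the dopamine transporter Slc6a3 from 0.474 to 39.1 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes were called, the smallest adjusted p being 0.266, for Wdr63, Hes5 and Rnaset2b; 1149 had an unadjusted p under 0.05, DESeq2 called 24 and voom 0. Wdr63 and the ribonuclease gene Rnaset2b had 0 counts in TG intranasal and were at least 20.6-fold and 44.3-fold lower than in TG drinking water. Both are low there, with means of 0.699 and 1.51 CPM. Rnaset2b is also among the chromosome 17 genes that set TG intranasal apart from all other libraries, which a shared stretch of that chromosome may account for.

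Lrrc17 was higher in TG mice given carnosine by either route, and it was the 1 gene called by edgeR in both comparisons with TG control; simulated groups with no change shared 0. That overlap was 0 without TG control 1 or 2, TG intranasal 2 or 3 or TG drinking water 1, 2 or 3, and 7 without TG control 3. With a term for the library split it was 1, a gene lower by both routes, and Lrrc17 was called by neither; in a fit of the compared libraries only, by voom and with a replicate block Lrrc17 was not called for nasal carnosine. At an unadjusted p under 0.01, 8 genes were higher and 44 lower by both routes, and 0 went opposite ways by edgeR. Independent lists of these sizes would share 0.466 and 3.603, and simulated groups that share the TG controls shared 11.9 and 6.90 on average. For the higher genes the shared controls alone gave more than the 8 seen, so that excess over independent lists is no sign of a common effect. For the lower genes the 44 seen lie above the highest simulated count of 12. The simulated genes were drawn independently of each other, with no library split and no trend with transcript length. The simulated counts are therefore no bound for these libraries, and the 44 are no evidence of a common effect of carnosine. The library split, which sets all treated TG libraries apart from TG control 1 and 2, may add to the 44. The controls could not be divided between the comparisons, since 3 libraries cannot be split into parts of at least 2 each.

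The last comparison sets the carnosine effects in TG against the genotype effect across genes. Thy1 was at 2.61 (SE 0.18) for genotype and at 0.22 (SE 0.17) and -0.0078 (SE 0.17) for nasal and oral carnosine. For nasal carnosine the covariance with the genotype effect was -0.112, against -0.0811 in simulated groups with no change that share the TG controls, a difference of -0.0314. For drinking water it was -0.0541 against -0.0815, a difference of 0.0274. The correlations across genes were -0.463 and -0.264, against -0.513 and -0.510 in the simulated groups, and genes are not independent replicates. The nasal covariance ranged from -0.211 (without TG control 1) to -0.0827 (without WT control 1) and the drinking-water covariance from -0.1497 (without TG control 1) to -0.0462 (without TG drinking water 1).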

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

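The tests of Lrrc17 against the library split and against WT mice were chosen after the result was seen, and the length and GC correction and matched lists after the data were seen. The log2 fold change between intranasal and control libraries differed between the genotypes for 367 genes, by the interaction test. With a term for the library split, which sets all TG intranasal libraries apart from all WT libraries, the count was 0, and after the length and GC correction it was 1. Among the genes named by the fixed rule, the log2 fold change in TG minus that in WT was 5.94 for Lrrc17, 4.01 for Tmem40, 3.90 for Bc1, 2.08 for Pcsk2os1, 1.65 for Fkbp1b, 1.34 for Nagk and 1.33 for Mrps11. It was -3.59 for Cdr1, -3.08 for Zbtb20, -2.32 for Hipk2, -2.26 for Slc2a12, -2.08 for Kcnq1ot1, -2.03 for Zfhx3, -1.35 for Tshz1 and -1.304 for Irf2bp2. The median difference was 1.63 for cytosolic ribosomal proteins, 1.298 for the respiratory chain, 0.95 for mitochondrial ribosomal proteins, 0.82 for antioxidant enzymes and 0.70 for the proteasome. It was -1.57 for immediate early genes, -1.11 for oligodendrocyte precursor markers, -1.09 for astrocyte markers and -0.75 for choroid plexus genes. Each of these lists passed camera at the preset correlation, with adjusted p of at least 0.650 with an estimated correlation.

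The interaction was compared with other splits of the same 12 libraries within genotypes. Of 100 splits, 3 called as many genes as the real split, itself included (367 against a highest other count of 547). The share is under 0.05, but other splits of the same libraries called as many, so chance is not excluded. Nor is a structure of the samples other than treatment, and the count moved with single libraries. Of the same splits, 85 called as many lists as the real 9, with up to 21, so chance cannot be excluded for the count of lists. The other comparisons have 10 splits each, too few for a share under 0.05. For genes, TG control against WT control called 2 (as many in 2 splits, highest other 175), WT intranasal against WT control 159 (1 split, highest other 1), TG intranasal against TG control 1 (2 splits, highest other 1), TG drinking water against TG control 1 (1 split, highest other 0) and TG intranasal against TG drinking water 0 (10 splits, highest other 0), all by edgeR. The split that called 175 genes set WT control 1 and 3 and TG control 1 against the rest, which points to a structure of the samples other than genotype. For lists in the same order, the real counts were 14, 12, 8, 17 and 18, with as many in 3, 6, 9, 4 and 2 splits and highest others of 17, 22, 19, 20 and 19.

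The respiratory-chain genes fell in WT intranasal, with a median log2 fold change of -0.86. WT control 1 alone is argued against, since the median was -0.638 without it and the upper quartile -0.450. Transcript length and GC content stay open: after a loess correction for both, the median was -0.169 with quartiles of -0.360 and -0.0496. Random lists matched on length, GC content and expression had a median of -0.582, with 95% between -0.690 and -0.473, above the real list in all 10000 draws. That interval measures the choice of genes and not the spread between libraries. It leaves out the correlation among respiratory-chain genes, so it decides nothing about a cause. A length bias and an effect of carnosine cannot be told apart for this list, because the correction left a median between the bounds set for either outcome.

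Lrrc17 was higher in the carnosine-treated TG libraries than in TG control. An effect of carnosine common to both genotypes is argued against, since Lrrc17 was at -1.84 (SE 0.53) in WT intranasal against WT control. A change of the whole region is argued against too, since the 10 nearest tested genes had a median of 0.147 in TG drinking water against TG control, with quartiles of -0.04 and 0.25. The library split and carnosine cannot be told apart for Lrrc17, because TG control 3 is the 1 untreated TG library on the side of the treated ones; with a term for the split Lrrc17 went from 4.09 (SE 0.58) to 3.54 (SE 0.90) for nasal and from 4.30 (SE 0.59) to 3.75 (SE 0.91) for oral carnosine and lost both calls (adjusted p = 0.452 and 0.105), as its error grew. TG control 3 had 8.30 CPM of Lrrc17, below the 16.7 to 147 CPM of the 6 treated libraries, and an effect of carnosine that needs the transgene stays open.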

How the results depend on the processing

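Named genes under the settings first planned for counts alone, the length and GC correction, the library-split term, fry, and leaving out the split's rows or the pituitary-rich libraries were chosen after the data were seen. Comparisons follow in the order TG control, WT intranasal, TG intranasal, TG drinking water, TG intranasal against TG drinking water, and interaction; the counts reported are 2, 159, 1, 1, 0 and 367 genes by edgeR (0 of 15818, with 1149 at an unadjusted p under 0.05). Where no cause is given, the cause was not tested. DESeq2 called 421, 1423, 14, 196, 24 and 2396, and 20 against 7 for genotype over control and intranasal libraries. Voom with weights called 2514 in WT intranasal, 0 in TG intranasal, 234 in TG drinking water and 1083 in the interaction. RLE scaling called 706 in the interaction (450 higher, 256 lower), and upper-quartile scaling 0 in WT intranasal. Without a filter the counts were 534, 5, 6 and 1276 in WT intranasal, TG intranasal, TG drinking water and interaction; at 5 CPM the interaction had 1301. At an adjusted p of 0.1 they were 1340, 2, 2 and 2880. In the compared groups only, which have fewer libraries, they were 1, 2, 0, 1, 1 and 0. The split term gave 0 in WT intranasal, 43 in TG drinking water (all lower, Lrrc17 not among them), 0 in the interaction and 2 for genotype over both treatments, and 13 lists both in TG intranasal and over both treatments. All WT libraries lie on the same side of the split, so the term cannot adjust WT intranasal against WT control. Without the split's rows there were 0 in WT intranasal and 3 for genotype over both treatments. The length and GC correction left 7 in WT intranasal, 1 in the interaction and 11 lists in TG drinking water. Without WT control 1 and TG control 1 there were 9 lists in TG control, 0 genes in WT intranasal, 91 in TG intranasal, 188 in TG drinking water and 669 in the interaction. With an estimated correlation or by fry, 0 lists were called in any comparison, against up to 18 by camera; at an unadjusted p under 0.05 the estimated correlation gave 1, 1, 0, 0, 2 and 0.

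The samples were not taken as paired by replicate number, which the labels do not explain. Of 30 same-number pairs, 12 correlated over 0.1, the lowest at -0.202, and 9 of 15 libraries correlated best with their own number. The median correlation was 0.0373 for same-number pairs and -0.0401 for the others. A factor shared by libraries of the same number is therefore not excluded. With a replicate block the counts were 531, 1587, 0, 2 and 2598 (TG intranasal against TG drinking water stayed at 0 by edgeR), and 3 lists for genotype over both treatments. The overlap of routes was 52 at an unadjusted p under 0.01, and the covariances over the 2 genes called for genotype were 0.0118 (nasal) and -0.0264 (drinking water), values that say nothing over so few genes.

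Leaving out each library gave 2 to 3, 0 to 960, 0 to 8, 0 to 8, 0 and 0 to 2389 genes, 4 to 9 for genotype over both treatments, and 0 to 7 shared by both routes. Lists ranged over 11 to 15, 12 to 14, 7 to 13, 12 to 22, 13 to 19 and 7 to 12, and 5 to 11 over both treatments. Covariances ranged from -0.211 to -0.0827 (nasal) and -0.150 to -0.0462 (drinking water). Reversed in some such fit were Btg2 (-0.061 to 2.14 in TG control, -2.17 to 0.029 in TG intranasal), Thy1 (-0.11 to 0.077), Gadl1 (-0.57 to 2.15) and Cbln3 (-0.39 to 3.87) in TG drinking water, Gadl1 between routes (-2.28 to 0.44) and Npas4 in the interaction (-3.85 to 0.21). The split term reversed Btg2 in TG intranasal (0.15) and Npas4 in the interaction (0.19). The length and GC correction reversed Tyrobp (0.028 in TG control, -0.070 in TG intranasal), Psmb3 (0.028 in WT intranasal, -0.075 in the interaction), Gsta4 (-0.0099 in TG intranasal) and Sod1 (-0.29 in the interaction). Thy1 in TG drinking water was also reversed by upper-quartile scaling (0.011), in the compared groups only (0.0026) and without both pituitary-rich libraries (0.024). Without those libraries Btg2 was at -0.079 in TG control and 0.029 in TG intranasal, and Npas4 at 0.42 in the interaction. No called list's median changed sign under RLE or upper-quartile scaling. For genotype, Thy1 kept its call in every alternative run. Pseudocounts, low-value filters and quantile scaling of normalised values were not run because the table holds counts. Depth limits genes with 0 counts in a group to lower bounds.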

Other observations

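The comparison of the genotypes over control and intranasal libraries, the choice of genes shared by both routes, the tests on chromosome 17 and the split test of lists for the genotypes were chosen after the results were seen. Over control and intranasal libraries together, Thy1 was higher in TG by a log2 fold change of 2.93 (SE 0.13). Markers of microglia rose with a median of 0.32 (camera adjusted p = 2.23e-06, adjusted p = 0.936 with an estimated correlation) and genes of microglial activation with 0.42 (camera adjusted p = 0.00349, adjusted p = 0.790 with an estimated correlation). Oligodendrocyte precursor markers rose with 0.18 (camera adjusted p = 0.0130, adjusted p = 0.936 with an estimated correlation) and meningeal fibroblast genes with 0.25 (camera adjusted p = 0.0442, adjusted p = 0.936 with an estimated correlation). Cerebellar genes were lower in TG with -0.77 (camera adjusted p = 0.0442, adjusted p = 0.936 with an estimated correlation). WT intranasal 2 and 3 stood apart, at 3.98 and 4.34 in mean log2 CPM of that list. WT control and WT intranasal 1 were at 1.09 to 1.58, within the 0.962 to 2.70 of TG control and TG intranasal. The lists that were lower in TG control than in WT control did not pass here (camera adjusted p from 0.194 to 0.927). Medians were -0.0181 for the respiratory chain, 0.0007 and -0.0090 for cytosolic and mitochondrial ribosomal proteins, 0.0107 for the proteasome and -0.0671 for antioxidant enzymes. In mean log2 CPM the respiratory chain was at 8.18 in WT control, against 7.34 to 7.93 in the other groups. Kcnk3, a potassium leak channel, was at -0.51 (SE 0.10) and did not pass (adjusted p = 0.149). The test called 7 genes by edgeR, 2 higher and 5 lower, with 772 at an unadjusted p under 0.05. The 5 lower ones were Mir6240 at -3.46, Mir6236 at -3.27, Lars2 at -3.20, an unnamed gene at -2.87 and Pcdh11x at -2.48, in libraries that also differ by the split. Of 100 splits within treatments, 4 called as many genes as the real 7, a share under 0.05 that does not exclude chance for the count. The 2 higher genes alone would give that share, so it says nothing of the 5 lower ones, of which 0 were called by edgeR with a term for the library split; a highest other count of 1296 points to a structure of the samples. Of the same splits, 96 called as many lists as the real 5, with up to 21, so chance cannot be excluded for the count of lists. The count was 4 without TG intranasal 2.

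Among the 52 genes with an unadjusted p under 0.01 and the same direction by both routes of carnosine in TG, some are named here, chosen after their values were seen. The scaffold gene Shank1 was at -1.19 (SE 0.32) for nasal and -1.22 (SE 0.32) for oral carnosine, Dlg4, which encodes PSD-95, at -0.62 (SE 0.19) and -0.80 (SE 0.19), and Dlgap3 at -0.67 (SE 0.23) and -0.98 (SE 0.23), and no list holding these 3 was tested. Lum, a proteoglycan of connective tissue, was at 0.79 (SE 0.26) and 0.82 (SE 0.26). None of these 4 passed the adjusted test by edgeR in either comparison, and all share the TG control libraries. All treated TG libraries lie on the low side of the library split with TG control 3, and TG control 1 and 2 on the other. The split and carnosine are therefore not separated for these genes. Lars2, Mir6236, Mir6240 and Cdr1, which follow the split, are among the 52. Spearman's rho with transcript length was -0.557 across genes for nasal and -0.195 for oral carnosine.

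Glo1 (gene ID 109801), which detoxifies methylglyoxal, was at 342 to 399 CPM in TG intranasal and at 144 to 279 CPM in the other 12 libraries, with a log2 fold change against TG control of 1.04 (SE 0.22) that did not pass (adjusted p = 0.406 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It was 1 of 19 genes among 785 on chromosome 17 (2.42%) whose TG intranasal libraries all lay outside the range of the rest, against 0.433% on the other chromosomes and 0.440% by chance. Rnaset2b, with 0 counts in TG intranasal, was among these 19. Chromosome 17 stood first of all, with an odds ratio of 5.70 (two-sided Fisher's exact test, adjusted p = 2.14e-06), so a stretch of chromosome 17 shared by these mice in a hybrid background may account for these genes. That test takes genes as independent, which neighbours on a chromosome need not be. For WT control too chromosome 17 had the highest odds ratio, of 1.72 (5.73% against 3.42%, same test, adjusted p = 0.0695). Intranasal carnosine acting alike in both genotypes cannot be told apart from a shared stretch. The genes' median log2 fold change, signed by direction in TG, was 0.181 in WT intranasal, but the genes were chosen for lying outside a range that includes the WT intranasal libraries, so this value decides nothing. A haplotype of the transgenic mice could not be read from counts and stays a hypothesis.

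Transcripts of neighbouring tissue marked single libraries. Omp of olfactory neurons was at 39.4 CPM and Cyp2a5 at 16.0 CPM in WT control 2. The striatal receptor Adora2a was at 90.6 CPM in TG control 3. The neutrophil gene S100a8 was at 9.37 and 11.6 CPM in TG drinking water 1 and 3. Malat1, a nuclear RNA, was at 556 to 1043 CPM in the 8 libraries on the high side of the split and 208 to 371 CPM in the other 7. Xist was at most 0.508 CPM and Ddx3y at 42.9 to 77.1 CPM in all 15 libraries, the pattern of males.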
